A study of Homo sapiens with 4 samples.

How the data were processed

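The series measured gene expression in MDA-MB-231 cells, an established human breast adenocarcinoma line, on 4 whole-transcript Affymetrix microarrays. Cells received 10 µM of PIP1, a pyrrole-imidazole polyamide (a synthetic ligand of the DNA minor groove), or the solvent DMSO alone, and RNA was taken after 48 hours. Each group held 2 arrays, numbered as replicates 1 and 2 by the labels. The series' design text calls these replicates technical, and no label ties them to separate cultures. All p-values therefore measure only the spread between these arrays, which may be technical.

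The authors deposited 1 table with an intensity for each of 53617 probe sets on each array. Per the submitters' processing notes it was made with Affymetrix Expression Console 1.3.1. The method of background correction, normalization and summary, the genome build and the probe set filter are not given in the sources used here. The deposited intensity values were on a linear scale, since they ran from 8.6e-06 to 7405 with none at or below 0. Between 2.10% and 3.33% of the values of an array lay below 1. Median intensities were similar but not equal, at 20.8 and 21.8 on the DMSO arrays and 19.5 and 19.7 on the PIP1 arrays. Arrays carry no read depth, and the number of arrays limits the precision.

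Values were taken to log2 without an offset. The platform annotation named 25713 of the probe sets. Of these, 23871 had 1 gene symbol and 1842 had several; the latter and the 27904 probe sets outside the annotation were not assigned to genes. The fixed design had expected log2 values and called for log2 to be taken first if they were linear. Symbols were updated through the Entrez identifier for 22569 of the single-symbol probe sets with NCBI RefSeq's gene table for GRCh38.p14, which changed 90 symbols. No genomic coordinates are printed, since the build behind the probe sets was not stated; gene spans and neighbour order come from that table. Where a gene had several probe sets (632 genes), the one with the highest mean log2 value was kept, giving 22395 genes. Genes whose mean over the 4 arrays lay below the 30th percentile, a log2 value of 4.11 or an intensity of 17.3, were not tested, which left 15676 genes.

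The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. PIP1 was compared with DMSO in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, group as the only term, a prior variance shared by all genes, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. Because 2 arrays against 2 give an exact permutation p of at least 0.333, no permutation test of single genes was run. An alternative set in advance let the prior variance follow the signal (eBayes with a trend). It is given beside the primary result throughout, because the 2 differed widely, and the choice to give it throughout was made after seeing the data. Standard errors are those of the primary fit. Background was not given with the values, so where a named gene's mean in 1 group lay under the filter intensity, its fold is printed as at least the brighter group's geometric mean over that intensity. This bound covers the dim group's level and not the spread between arrays, and it was chosen after seeing the data. The 26 fixed lists (506 of 637 members tested, at least 5 per list) were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. The same test with an estimated correlation, camera on ranks and fry were alternatives.

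The named genes are MECOM, REL and ELK1; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with both PIP1 arrays on the same side of both DMSO arrays, or, if none passed, the 5 with the smallest p in each direction. Placeholder symbols, small nucleolar, micro and transfer RNA genes and immune receptor segments were left out of that choice. Each fixed list adds the 2 members with the smallest p, or for a list past the list test up to 4 members past the gene threshold. Since no gene passed the primary test, the same rule was also applied to the fit with the signal trend, and up to 4 members of each list past its threshold were named. Histone, metallothionein and ribosomal protein genes have near-identical copies, as does the 5S ribosomal RNA family, and their probe sets may share signal.

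The other alternatives were no filter, a filter at the 50th percentile, quantile normalization, centring on array medians, a robust prior, a test without moderation, the mean of a gene's probe sets, all probe sets, the replicate number as a block, and leaving out each array. An offset of 16 before log2, removal of each array's loess trend (smoothing span 0.5) with genomic span, and the combinations with the signal trend were added after seeing the data. On data simulated for PIP1 against DMSO over 15676 genes with 200 changed, the primary test recovered 3% of the changes of log2 1 and 86% of those of log2 2. With the signal trend it recovered 58% and 98%, with 4 false calls among 160. The simulated spread was drawn from the trend fit's own prior, alike in both groups and independent between genes, which favours that fit. In the data the median absolute difference was 0.15 between the PIP1 arrays and 0.26 between the DMSO arrays. The simulation therefore does not measure the error of the real calls. In a simulation of 26 lists of independent genes, 1 list of 30 genes shifted by 0.4 (log2) was called and 0 of the others were. Figures were drawn with matplotlib 3.10.9.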

Results

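Expression was profiled in 4 arrays of MDA-MB-231 cells, 2 from cells treated with 10 µM PIP1 for 48 hours and 2 from cells given the solvent DMSO. The series addressed the effect of a polyamide directed at the overlapping REL and ELK1 sequences of the EVI1 minimal promoter. Over 15676 tested genes, Pearson's r between log2 values was 0.985 for the PIP1 arrays and 0.976 for the DMSO arrays, and between 0.961 and 0.968 for the 4 pairs of a PIP1 with a DMSO array. The median absolute difference was 0.15 (log2) between the PIP1 arrays, 0.26 between the DMSO arrays and from 0.33 to 0.36 between groups. The median log2 fold change over all tested genes was -0.03.

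MECOM, which encodes the zinc finger transcription factor EVI1 and was the gene PIP1 was directed at, had lower signal on both PIP1 arrays than on both DMSO arrays. Its intensity was 359.6 and 357 with DMSO and 233 and 185 with PIP1, a 1.72-fold lower geometric mean. The log2 fold change was -0.79 ± 0.19 (SE), with a 95% confidence interval from -1.25 to -0.32. limma's p was 0.0059 and the adjusted p was 0.156 in the primary fit, which did not pass the threshold, and 0.0045 with the signal trend. MECOM's log2 fold change was -0.95 without PIP1 replicate 1, -0.62 without PIP1 replicate 2, -0.78 without DMSO replicate 1 and -0.79 without DMSO replicate 2. Whether it passed the trend fit depended on which array was left out. Such a fit takes its spread from the other group's arrays alone, so no p-value is given for it here. With each array's trend on genomic span removed, the log2 fold change was -0.39, and 46 of the 200 protein-coding genes closest to MECOM in span had a lower fold change than MECOM. Span here is that of the whole gene, and which MECOM transcripts its 1 probe set measures is not known. REL, a subunit of NF-kB, had a log2 fold change of -0.38 ± 0.17 (SE, adjusted p = 0.24 in limma). ELK1, an ETS-family transcription factor, had one of 0.38 ± 0.17 (SE, adjusted p = 0.24 in limma). Neither passed with the signal trend over all arrays (adjusted p = 0.17 and 0.089). With each array left out the log2 fold change lay between -0.46 and -0.30 for REL and between 0.32 and 0.44 for ELK1. Whether they passed the trend fit then depended on which array was left out.

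**Figure D1:**
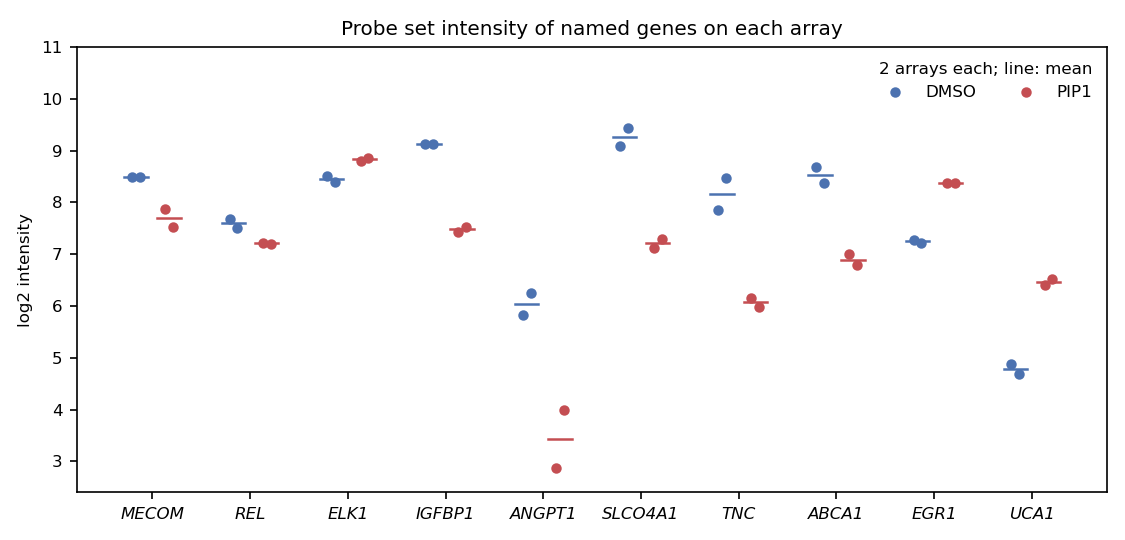
Log2 intensity (vertical axis) of 10 named genes (horizontal axis) on each of the 2 DMSO and 2 PIP1 arrays, with a line at each group's mean. Both PIP1 arrays lie below both DMSO arrays for MECOM, REL, IGFBP1, ANGPT1, SLCO4A1, TNC and ABCA1, and above them for ELK1, EGR1 and UCA1; the PIP1 values of ANGPT1 lie under 4.11, the level of the filter on dim genes.

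Among the genes that differed most between the groups, SLCO4A1, ANGPT1, TNC and IGFBP1 had lower signal with PIP1 and UCA1, ROPN1L and FGFR3 had higher signal. In the primary limma fit 0 genes were higher and 0 lower at an adjusted p under 0.05, the smallest adjusted p being 0.106. At an unadjusted p under 0.05 there were 1666 higher and 1948 lower genes, where chance gives 784 in all. Both PIP1 arrays lay above both DMSO arrays for 4492 genes and below them for 4767, or 59.1% of genes, where chance gives 33.3%. Any difference between the groups' arrays, technical or not, raises both of these counts, and genes are not independent. The excess over chance alone therefore does not show an effect of PIP1. With the prior variance following the signal, limma called 909 genes higher and 1007 lower, of which 44 rose and 207 fell at least 2-fold, or 14 and 79 with an offset of 16. These counts depended on which array was left out. They were 16 higher and 108 lower without PIP1 replicate 1, 15 and 99 without PIP1 replicate 2, 2823 and 2430 without DMSO replicate 1, and 2322 and 2210 without DMSO replicate 2. Centring arrays on their medians moved the median of all genes to 0.09 and gave 2035 higher and 566 lower genes with the signal trend, or 78.2% higher in place of 47.4%. In the trend fits with an array left out the prior degrees of freedom were infinite, so a gene's own spread between replicates carried no weight. A call in each of these fits therefore does not show that a gene's arrays agreed. MUC1 was called in all of them with log2 values of 7.24 and 9.18 on DMSO replicates 1 and 2. The trend fit over all arrays had 26.5 prior degrees of freedom against 2 residual ones, so there too a gene's own spread carried little weight. DNAH3 had log2 values of 5.00 and 8.48 on the DMSO arrays, yet its adjusted p in limma with the signal trend was 0.017. Genes are described below as having risen or fallen where the adjusted p with the signal trend was under 0.05. None of them passed the primary fit.

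The 5 lower genes with the smallest p in the primary fit were SLCO4A1-AS1, SLCO4A1, UBOX5-AS1, IGFBP1 and PDE4B. SLCO4A1, an organic anion transporter, fell from a mean intensity of 622 to 149 (log2 fold change -2.06 ± 0.20 SE, adjusted p = 9.9e-09 with the signal trend). Its antisense transcript SLCO4A1-AS1 fell from 108 to a PIP1 level under the filter intensity of 17.3, at least 6.27-fold lower; the 2 genes overlap, and how far their probe sets share signal is not known. IGFBP1, a secreted binding protein of insulin-like growth factors, fell from 562 to 178 (-1.66 ± 0.17 SE). PDE4B, a cyclic AMP phosphodiesterase, and UBOX5-AS1, an antisense RNA, also fell to levels under 17.3, from 44.5 (at least 2.57-fold lower) and 36.5 (at least 2.10-fold lower). The 5 higher genes with the smallest p were UCA1, ROPN1L, FAM222A, FGFR3 and LUARIS. UCA1, a long non-coding RNA, rose from 27.6 to 88.3 (1.68 ± 0.18 SE, adjusted p = 0.00037 with the signal trend). ROPN1L rose from 53.9 to 163 (1.62 ± 0.22 SE), FAM222A from 54.7 to 141 (1.37 ± 0.19 SE), the growth factor receptor FGFR3 from under 17.3 to 43.0 (at least 2.49-fold higher) and LUARIS from 26.2 to 60.2. All 10 had an adjusted p of 0.106 or 0.153 in the primary limma fit.

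By size, and leaving out the classes of symbol that the rule for named genes excludes, the 12 largest fitted falls in the trend fit were SLCO4A1-AS1, ANGPT1, SLCO4C1, ATP6V0D2, TNC, SLCO4A1, DNAH3, UBOX5-AS1, DEPP1, TNFSF15, H2BC1 and KYNU. Their order is not exact, since SLCO4A1-AS1, ANGPT1, SLCO4C1, ATP6V0D2, UBOX5-AS1, DEPP1 and KYNU had PIP1 means under the filter intensity and background was not measured. ANGPT1, the angiopoietin ligand of the TEK receptor, was at least 3.82-fold lower (limma adjusted p = 8.9e-05 with the signal trend, 0.153 in the primary fit), and SLCO4C1, another organic anion transporter, at least 2.71-fold lower (0.00021 and 0.153). The bound was 2.17-fold for ATP6V0D2, 2.47-fold for DEPP1 and 2.81-fold for KYNU. TNC, the matrix glycoprotein tenascin C, fell by 2.09 ± 0.25 (SE, adjusted p = 8.8e-07 with the signal trend), and TNFSF15, a cytokine of the tumour necrosis factor family, fell by 1.83 ± 0.50 (SE). Without DMSO replicate 1 and without DMSO replicate 2 the log2 fold change was -2.65 and -1.01 for TNFSF15, and -3.76 and -0.28 for DNAH3, an axonemal dynein. The 12 largest fitted rises were UCA1, ROPN1L, RN5S99, EFR3B, LINC00899, FGFR3, FAM222A, CHI3L2, CCL5, CASTOR2, SLC27A2 and KCNJ14, in an order that is not exact, since RN5S99, FGFR3 and KCNJ14 had DMSO means under the filter intensity. The bound on the fold was 1.90 for RN5S99 but 1.33 without DMSO replicate 2, and 1.54 for KCNJ14 but 1.09 without PIP1 replicate 1. CCL5, a chemokine, rose by 1.35 ± 0.25 (SE, adjusted p = 0.0012 with the signal trend) and SLC27A2, a fatty acid transporter, by 1.31 ± 0.41 (SE, adjusted p = 0.022). Without DMSO replicate 1 and without DMSO replicate 2 the log2 fold change was 1.87 and 0.74 for SLC27A2, and 0.94 and 2.01 for LINC00899. RN5S99 belongs to a family of near-identical copies. Of these 24 genes, DNAH3, TNFSF15, RN5S99, LINC00899, SLC27A2 and KCNJ14 had a log2 fold change that moved by over 1.5 times when an array was left out.

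**Figure D2:**
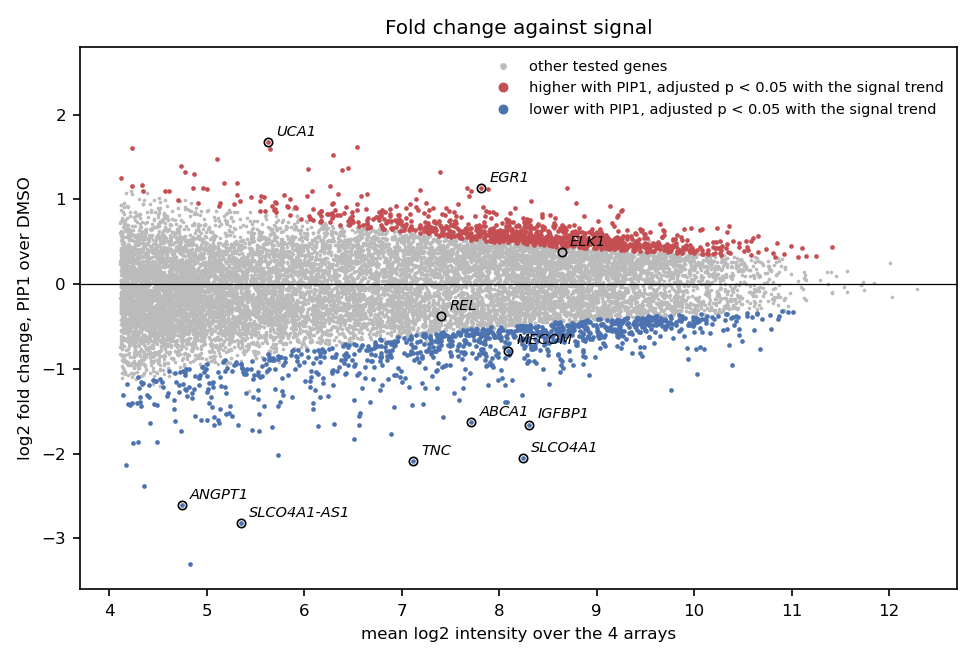
Log2 fold change of PIP1 over DMSO (vertical axis) against the mean log2 intensity over 4 arrays (horizontal axis) for 15676 genes. Coloured points are the 909 higher and 1007 lower genes of the fit with the signal trend, circles mark named genes, and REL and ELK1 lie among the genes not called.

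Of the 26 fixed lists, 3 were shifted higher with PIP1 and 2 lower in camera at the preset correlation, and none of the 26 held with an estimated correlation. With an estimated correlation camera's p rests on 2 residual degrees of freedom here, which leaves little power. Failing it does not show that correlation between genes accounts for a shift, and that question stays open. For oxidative phosphorylation the estimate was -0.0017, below the preset 0.01, yet camera's p went from 0.0028 to 0.080. The estimate was 0.56 for DNA replication and 0.17 for ELK1/SRF immediate early genes, far above the preset that their adjusted p rests on. For transporter and mesenchymal genes it was 0.012 and -0.011. DNA replication genes lay higher (median log2 fold change 0.28, 31 of 38 members above 0, adjusted p = 0.0037), with adjusted p = 0.82 with an estimated correlation. In the trend fit 7 of them rose and 0 fell, among them the transcription factor E2F1 (0.73 ± 0.18 SE), the cyclin CCNE1 (0.71 ± 0.21), the licensing factor CDT1 (0.66 ± 0.18) and the helicase subunit MCM2 (0.62 ± 0.17). Nuclear-encoded oxidative phosphorylation genes lay higher (median 0.28, 19 of 24 above 0, adjusted p = 0.022), with adjusted p = 0.77 with an estimated correlation. In that list 4 rose and 0 fell, namely the respiratory chain subunits NDUFB3 (0.48 ± 0.18), NDUFA1 (0.46 ± 0.18), COX4I1 (0.42 ± 0.16) and CYC1 (0.40 ± 0.19). The ELK1/SRF immediate early list holds SRF and ELK1 targets and other immediate early genes, so it does not test ELK1 targets alone. Its members lay higher (median 0.27, 16 of 23 above 0, camera adjusted p = 0.022), with adjusted p = 0.77 with an estimated correlation. Of these 7 rose and 1 fell. EGR1, an early growth response factor, rose by 1.13 ± 0.17 (SE), MYC by 0.56 ± 0.18, CCN2 by 0.55 ± 0.30 and SRF by 0.52 ± 0.19, while ATF3 had 0.80 ± 0.23 and an adjusted p of 0.081. Without DMSO replicate 1 and without DMSO replicate 2 the log2 fold change was 0.98 and 0.11 for CCN2, 0.69 and 0.35 for SRF, 0.95 and 0.47 for CCNE1, and 0.57 and 0.23 for CYC1.

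Drug transporter genes lay lower (median -0.44, 10 of 12 below 0, adjusted p = 0.022), with adjusted p = 0.77 with an estimated correlation. In the trend fit 3 fell and 0 rose: SLCO4A1, ABCA1, which exports cholesterol (-1.63 ± 0.20 SE), and ABCC4 (-0.59 ± 0.20). Mesenchymal genes lay lower (median -0.40, 17 of 24 below 0, adjusted p = 0.028), with adjusted p = 0.77 with an estimated correlation. Of these 6 fell and 1 rose. TNC, the matrix protein FN1 (-0.95 ± 0.24 SE), the collagen crosslinking enzyme LOX (-0.91 ± 0.26) and the transcription factor ZEB1 (-0.58 ± 0.16) were among those that fell; LOX was at -1.25 without DMSO replicate 1 and -0.57 without DMSO replicate 2. Adjusted over the list alone, the primary fit called 0 DNA replication, 0 oxidative phosphorylation, 1 immediate early, 3 transporter and 1 mesenchymal gene. The members of these lists named here were chosen after their values were seen, since none passed the primary gene threshold. Over all tested genes the trend fit called 1916 of 15676. By signal it called from 28 of 1568 genes in the dimmest decile to 353 of 1568 in the brightest. The counts of called list members were not compared with genes of like signal, so they do not set a list apart. The DMSO arrays themselves differed: replicate 2 minus replicate 1 had a median of -0.27 for DNA replication, -0.16 for immediate early, -0.07 for oxidative phosphorylation, 0.01 for transporter and 0.22 for mesenchymal genes. Without DMSO replicate 2 none of the 5 lists passed. Their medians were then 0.16 for DNA replication, 0.26 for oxidative phosphorylation, 0.18 for immediate early, -0.29 for transporter and -0.24 for mesenchymal genes. Oxidative phosphorylation did not pass without PIP1 replicate 2 either (0.23), nor did the mesenchymal list without DMSO replicate 1 (-0.47). With the span trend removed only DNA replication passed (camera adjusted p = 0.014). The other lists of the 5 kept their direction, with camera adjusted p from 0.068 to 0.12.

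**Figure D3:**
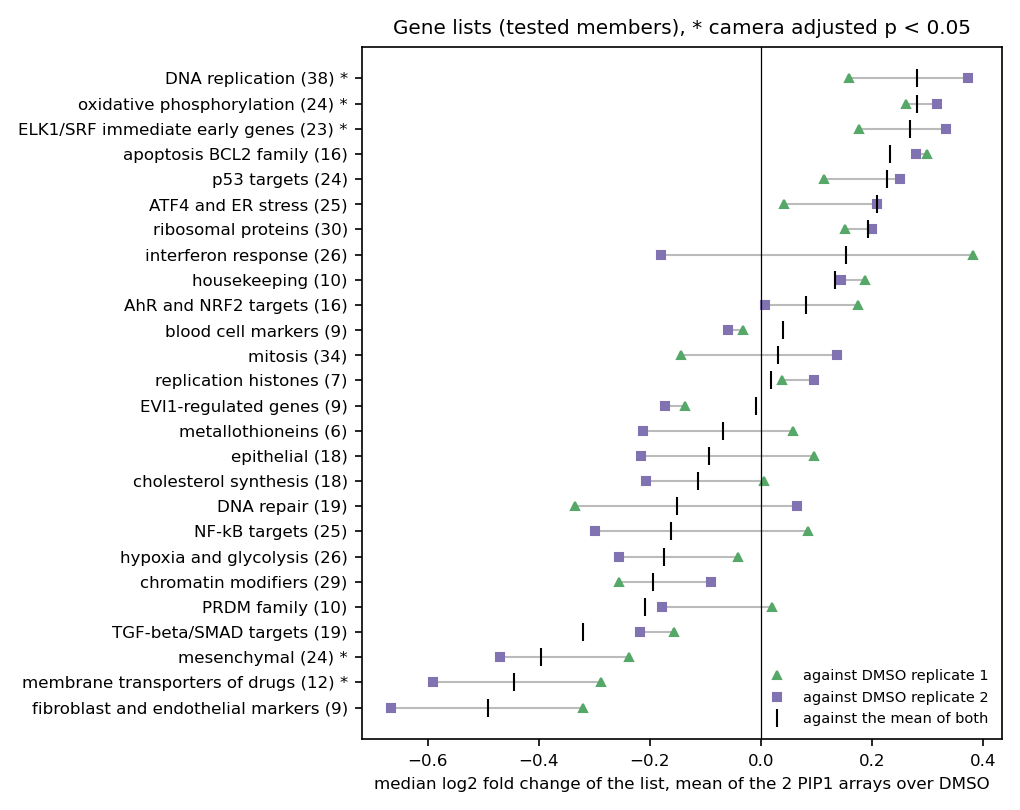
Median log2 fold change (horizontal axis) of each fixed list (vertical axis, number of tested members in parentheses) for the mean of the 2 PIP1 arrays against DMSO replicate 1, DMSO replicate 2 and their mean. An asterisk marks the 5 lists with a camera adjusted p under 0.05, and the interferon list lies at 0.38 against replicate 1 and -0.18 against replicate 2.

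Of 9 tested genes described elsewhere as EVI1-regulated, 4 fell and 0 rose with the signal trend: ANGPT1, CDH1 (-1.44 ± 0.28 SE), the adhesion receptor ADGRG1 (-1.36 ± 0.26) and the integrin ITGA6 (-0.71 ± 0.18). The primary fit's p-values adjusted over the list alone also gave 4 lower, whereas the list's median was -0.01 and its camera adjusted p was 0.33. Such calls use the same arrays and are not adjusted over the 26 lists, of which 11 held at least 1. Both PIP1 arrays lay above both DMSO arrays for 3 of these genes and below them for 4. The list mixes genes described as regulated in either direction, so no common sign is implied. In the PRDM family, to which MECOM belongs, the median was -0.21 over 10 members (adjusted p = 0.62); PRDM8 fell (-0.73 ± 0.17) and PRDM13 had -0.64 ± 0.19. NF-kB targets split, with 3 higher and 3 lower of 25 (median -0.16, camera adjusted p = 0.53): CCL5 and NFKB2 (0.89 ± 0.17) rose, and the chemokines CXCL8 (-0.99 ± 0.19) and CCL2 (to under the filter intensity, at least 1.76-fold lower) fell. Adjusted over the list alone there were 2 higher and 3 lower. TGF-beta targets had 4 higher and 1 lower of 19 (median -0.32, adjusted p = 0.65), and those higher were the differentiation inhibitors ID3 (1.14 ± 0.18) and ID1 (0.55 ± 0.18), the kinase inhibitor CDKN1A (0.59 ± 0.24) and CCN2. Here 1 member was called higher adjusted over the list alone. CDKN1A was at 0.29 without DMSO replicate 1 and 0.89 without DMSO replicate 2.

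None of the further lists passed camera. Mitosis genes had a median of 0.03 and a mean of -0.02 (34 tested, adjusted p = 0.97), with 2 higher (NEK2, 0.49 ± 0.20 SE; AURKB, 0.39 ± 0.18) and 1 lower (ASPM, -0.55 ± 0.18), and PTTG1 at -0.69 ± 0.26 (-0.35 without PIP1 replicate 1). NEK2 was at 0.67 without DMSO replicate 1 and 0.30 without DMSO replicate 2. DNA repair genes (median -0.15, 19 tested, adjusted p = 0.65) had 2 higher (XRCC3, 0.76 ± 0.18; FANCG, 0.55 ± 0.19) and 2 lower (BRIP1, -0.65 ± 0.17; CHEK1, -0.54 ± 0.18). The p53 targets (median 0.23, 24 tested, adjusted p = 0.33) had 4 higher, AEN (0.92 ± 0.25), GADD45A (0.63 ± 0.17), CDKN1A and PMAIP1 (0.45 ± 0.18), and 1 lower. ATF4 and ER stress genes (median 0.21, 25 tested, adjusted p = 0.33) had 4 higher and 2 lower. SDF2L1 rose by 0.81 ± 0.23 and PPP1R15A by 0.76 ± 0.17, while DDIT4 fell by 0.80 ± 0.19 and VEGFA by 0.70 ± 0.17. In the BCL2 family (median 0.23, 16 tested, adjusted p = 0.091) BCL2L12 (0.77 ± 0.18) and PMAIP1 rose, and BCL2L11 had 0.68 ± 0.19. Replication histones (median 0.02, 7 tested, adjusted p = 0.62) had no call; H2BC21 was at 0.44 ± 0.17 and H2BC14 at -0.36 ± 0.18 (-0.23 without PIP1 replicate 2).

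In cholesterol synthesis 5 fell and 0 rose (median -0.11, 18 tested, adjusted p = 0.34), among them the desaturase SCD (-1.25 ± 0.29 SE), INSIG1 (-1.04 ± 0.21), STARD4 (-0.74 ± 0.17) and HMGCS1 (-0.58 ± 0.27, from -0.86 to -0.30 with each array left out), with 3 lower adjusted over the list alone. Epithelial genes had 1 higher and 5 lower (median -0.09, 18 tested, adjusted p = 0.50), with MUC1 (-1.57 ± 0.59, but -2.53 without DMSO replicate 1 and -0.60 without DMSO replicate 2), TFF1 (-1.47 ± 0.21), CDH1 and CLDN7 (-1.08 ± 0.26) lower and CLDN3 (0.89 ± 0.17) higher. Adjusted over the list alone, 1 was higher and 3 lower. Hypoxia and glycolysis genes (median -0.17, 26 tested, adjusted p = 0.33) had 1 higher, ADM (0.98 ± 0.18), and 3 lower, LOX, VEGFA and ERO1A (-0.46 ± 0.17), and 1 higher adjusted over the list alone. AhR and NRF2 targets (median 0.08, 16 tested, adjusted p = 0.50) had 3 higher, SRXN1 (0.66 ± 0.18 for the brighter of its 2 probe sets, -0.50 for the other), GCLM (0.51 ± 0.17) and FTL (0.44 ± 0.18), and 1 lower, UGDH (-0.42 ± 0.18). OSGIN1 was at 0.67 ± 0.17. Chromatin modifiers (median -0.19, 29 tested, adjusted p = 0.21) had 1 higher and 6 lower, including the DNA demethylases TET1 (-1.23 ± 0.19) and TET2 (-0.62 ± 0.19) and the histone demethylases KDM5B (-0.63 ± 0.17) and KDM5A (-0.56 ± 0.21), with 1 lower adjusted over the list alone. KDM6B was at 0.74 ± 0.19. Interferon-stimulated genes (median 0.15, 26 tested, adjusted p = 0.61) had 4 higher, such as IFI6 (0.62 ± 0.23), and 3 lower, XAF1 (-0.82 ± 0.20), IFITM1 (-0.73 ± 0.25) and IRF9 (-0.71 ± 0.29 for the brighter of its 2 probe sets, -0.011 for the other), with USP18 at 0.62 ± 0.19. Without DMSO replicate 1 and without DMSO replicate 2 the log2 fold change was 0.35 and 0.90 for IFI6, -1.05 and -0.41 for IFITM1, and -1.09 and -0.33 for IRF9. DMSO replicate 2 lay above replicate 1 in that list by a median of 0.48.

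Ribosomal protein genes (median 0.19, 30 tested, adjusted p = 0.17) had 5 higher and 1 lower, with RPS19 (0.51 ± 0.17 SE), RPL18 (0.44 ± 0.17) higher and RPS23 (-0.75 ± 0.20) lower. The brighter of the 2 probe sets of RPS28 was also higher (0.49 ± 0.19, but 0.31 without DMSO replicate 1), whereas the other was at -0.44. Reference genes (median 0.13, 10 tested, adjusted p = 0.33) had no call; POLR2A was at 0.34 ± 0.17 and ACTB at 0.34 ± 0.19 (0.21 without PIP1 replicate 2). Metallothioneins (median -0.07, 6 tested, adjusted p = 0.98) had no call, with MT1E at 0.44 ± 0.20 (0.24 without DMSO replicate 2) and MT1H at -0.46 ± 0.26 (-0.15 without PIP1 replicate 1 and -0.78 without PIP1 replicate 2). Among markers of other cell types, leukocyte genes had a median of 0.04 and a mean of -0.17 (9 tested, adjusted p = 0.78), and LYZ fell (-1.73 ± 0.41, but -2.34 without DMSO replicate 1 and -1.11 without DMSO replicate 2), with CD14 at -0.73 ± 0.17 and 2 lower adjusted over the list alone. Fibroblast and endothelial genes had a median of -0.49 (9 tested, adjusted p = 0.21), and KDR (-0.77 ± 0.22) and COL1A2 (to under the filter intensity) fell. The bound on the fold of COL1A2 was 2.44 with all arrays but 1.63 without DMSO replicate 2. DMSO replicate 2 lay above replicate 1 in the latter list by a median of 0.33. The median changed sign after quantile normalization for EVI1-regulated genes (0.12), metallothioneins (0.01), mitosis (-0.01) and replication histones (-0.02). It did so after median centring for EVI1-regulated (0.11), cholesterol synthesis (0.01), epithelial (0.03) and metallothionein (0.05) genes. Against DMSO replicate 1 and DMSO replicate 2 in turn, the list median was 0.38 and -0.18 for interferon-stimulated genes, 0.08 and -0.30 for NF-kB targets, 0.10 and -0.22 for epithelial and -0.33 and 0.06 for DNA repair genes. It was -0.14 and 0.14 for mitosis, 0.0048 and -0.21 for cholesterol synthesis, 0.06 and -0.21 for metallothionein and 0.02 and -0.18 for PRDM genes, so that no direction is given for these lists. Against 1 DMSO replicate or both, it also moved by over 1.5 times from the median with all arrays for AhR and NRF2 targets (0.17 and 0.0074). So it did for ATF4 and ER stress (0.04 and 0.21) and p53 targets (0.11 and 0.25). The same held for hypoxia (-0.04 and -0.26), chromatin modifiers (-0.26 and -0.09), and TGF-beta targets (-0.16 and -0.22). It held as well for fibroblast and endothelial (-0.32 and -0.66), EVI1-regulated (-0.14 and -0.17) and replication histone genes (0.04 and 0.10). Among the lists past camera, it held against DMSO replicate 1 for DNA replication (0.16), mesenchymal (-0.24), transporter (-0.29) and immediate early genes (0.18). Leukocyte genes had medians of -0.03 and -0.06 against the DMSO replicates in turn but 0.04 with all arrays, so no direction is given for that list either.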

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

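The offset, removal of the span trend and all combinations with the signal trend were chosen after the result was seen. MECOM, REL and ELK1 kept their direction under each alternative run, and REL and ELK1 stayed above the threshold in the primary fit's alternatives; no called list reversed. In the primary fit the counts of 0 higher and 0 lower genes became 13 and 41 (13 and 40 at least 2-fold) with the filter at the 50th percentile, 93 and 242 (13 and 77) with an offset of 16, and 909 and 1007 (44 and 207) with the prior following the signal. With the replicate number as a block they became 22 and 120, all at least 2-fold; deviations of same-numbered arrays correlated at -0.03, so the numbers were not taken to pair the arrays. Leaving out each array gave from 0 to 18 higher and from 0 to 115 lower genes, again all at least 2-fold, in which a lone array is assumed to vary like the other group. No filter, quantile normalization, median centring, a robust prior, probe set means, all probe sets, the unmoderated test and removal of the span trend each gave 0. The share of higher genes among those at an unadjusted p under 0.05 was 46.1% as reported, 72.1% after median centring and 35.4% over all probe sets; after centring these were 2818 higher and 1092 lower genes. MECOM passed the threshold with an offset (-0.74, adjusted p = 0.049) and with the signal trend (-0.79), and its adjusted p ranged up to 0.47 over the alternatives. With the signal trend, counts moved to 409 higher and 508 lower without a filter and to 2035 and 566 after median centring, and the lower count to 575 without the span trend; leaving out each array gave from 15 to 2823 higher and from 99 to 2430 lower genes. Genes at least 2-fold higher there ranged from 14 to 121 and at least 2-fold lower from 79 to 371 over the alternatives, with 14 and 79 at an offset of 16. The block gave 731 higher and 884 lower genes there. The 3 lists shifted higher and 2 shifted lower became 0 and 0 with an estimated correlation and with fry (in which 9 lists had an unadjusted p under 0.05). They became 3 and 0 without a filter, 1 and 2 after quantile normalization and 1 and 0 without the span trend. Leaving out each array gave from 0 to 3 lists higher and from 0 to 4 lower, with 0 and 0 without DMSO replicate 2. The cause was not tested. Among named genes, 248 of the alternative values passed the threshold where the primary did not and 1412 kept their side. Background was not measured, so how far it limits calls among dim genes is not known.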

Other observations

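The tests of the DMSO arrays, of MECOM's span, of the spread against signal and of the other splits were chosen after the result was seen, as were the gene families; the tests of span over all genes and in small nucleolar RNA genes were written down before their result was computed. Grouping tested genes by the letters of their symbol gave 202 families of at least 10 members, of which 8 lay higher and 3 lower with PIP1 in camera at the preset correlation. None of these held with an estimated correlation (smallest adjusted p = 0.89), a test that 2 residual degrees of freedom left with little power. The C/D-box small nucleolar RNA genes (SNORD) were the first, with 55 of 63 above 0, a median log2 fold change of 0.34 and an adjusted p of 5.0e-06. RNA polymerase subunit genes (POLR) had 26 of 30 above 0 (median 0.36, adjusted p = 0.00078), and mitochondrial ribosomal protein genes MRPL had 40 of 48 (median 0.31, adjusted p = 0.00088). The protocadherin beta genes PCDHB, adhesion genes that are close relatives of one another, had 10 of 10 below 0 (median -0.88, adjusted p = 0.00088), and the DENND guanine nucleotide exchange genes 17 of 17 (median -0.44, adjusted p = 0.00088). Whether near-identical members share probe signal was not tested; 7 of these families also passed with the span trend removed, PCDHB among them with a median of -0.94.

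The tested genes next to MECOM in chromosomal order were looked at after its value was seen. On one side, from the nearest outward, TERC had a log2 fold change of 0.12 ± 0.18 (SE) and ACTRT3 of -0.52 ± 0.32. Then came MYNN with -0.61 ± 0.17 (limma adjusted p = 0.16, 0.040 with the signal trend) and LRRC34 with -0.64 ± 0.23. On the other side, in the same order, MIR551B had 0.04 ± 0.24, GOLIM4 -0.08 ± 0.21, SERPINI1 0.51 ± 0.20 and PDCD10 -0.17 ± 0.19. Apart from MYNN none of these neighbours passed with the signal trend.

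Genes with long genomic spans had lower fold changes. Across 15352 genes, which are not independent replicates, Spearman's rho between span and log2 fold change was -0.235. Over 13458 protein-coding genes the median went from 0.13 in the shortest quintile, with 279 genes called higher and 66 lower by the signal trend, to -0.28 in the longest, with 38 and 493. A difference in signal level is argued against by a partial rho of -0.268 given the mean signal. Whether PIP1 or a technical axis sets the trend cannot be told apart, since the DMSO arrays differed along it too (rho = -0.135) and the weakest contrast of a PIP1 with a DMSO array was -0.139.

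The whole MECOM gene has a span of 580 kb, and 23% of the 200 protein-coding genes closest to it in span had a lower fold change, their median being -0.48. The length transcribed from the EVI1 promoter was not used, so these genes may not match it in length. The 106 small nucleolar RNA genes had a median of 0.33, and of 0.317 with the span trend removed; it was 0.21 against DMSO replicate 1 and 0.36 against DMSO replicate 2, and DMSO replicate 2 minus replicate 1 had a median of -0.17.

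The DMSO arrays, described as technical replicates, differed in sets of related genes. Replicate 2 lay above replicate 1 by a median of 0.48 (interquartile range 0.27 to 0.68) for 26 interferon-stimulated genes, and the median for 34 mitosis genes was -0.27 (-0.37 to -0.16). Scaling is argued against by medians of 0.495 and -0.269 after quantile normalization, and gene span by 0.452 and -0.294 with its trend removed. The labels give no group that parts these arrays, and no biological explanation was tested.

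The number of called genes depended on how the spread was modelled. The median pooled SD was 3.01 times higher in the dimmest than in the brightest decile of tested genes, which is consistent with a shared prior overstating the spread of bright genes. With the signal trend, calls went from 28 in the dimmest decile to 353 in the brightest. Of the 3 splits of the arrays into 2 against 2, only 1, the real one, gave 1916 calls, and the highest of the others was 1. In the primary fit the real split gave 0 calls and the highest of the others 2. The other splits mix PIP1 and DMSO arrays on each side, so any group difference, whatever its cause, enters their spread. With the signal trend they gave 103 and 136 genes at an unadjusted limma p under 0.05, where chance gives 784. The contrast between splits is therefore no support for the calls. With 3 splits a share under 0.05 cannot be reached.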
